A study of Homo sapiens with 12 samples.

How the data were processed

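RNA sequencing was done on 12 libraries of the SW480 colorectal cancer cell line: 4 each of the early fraction F1, the late fraction F3 and the total eluted population PT from sedimentation field-flow fractionation. Per the labels' protocols, RNA was isolated with the Quick-RNA Microprep kit (Zymo Research), samples with an RNA integrity number above 7 were kept, and paired-end reads were made on a DNBSEQ instrument. The labels place all libraries in one batch. They describe independent cultures, so the spread between libraries includes that between cultures.

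The authors deposited one table of gene counts per library, as whole numbers with Entrez gene identifiers. Per the submitters' processing notes, HISAT2 2.2.1, Bowtie2 2.3.4.3, Bowtie2 2.4.5, RSEM 1.3.1 and the build GRCh38.p14 were used, with no role or order given for each tool. The annotation, the strand setting of the counting and any rounding of estimated counts are not given in the sources used here. Genes that overlap or share most of their sequence, such as ANXA8L1 and BMI1, are reported as uncertain. The table held 18856 genes, of which 18844 matched a RefSeq gene of GRCh38.p14 by identifier; the other 12 held 0.000124% of the counts. Gene symbols and coordinates come from that RefSeq table. Almost all the genes were protein-coding, and 13 were mitochondrial mRNAs.

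Totals were between 29030028 and 30453559 counts per library. Pairs of replicates were compared by a chi-square statistic over genes with a summed count of at least 10; it was 18.98 to 362 per degree of freedom, so no 2 replicates were near-duplicates.

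Groups came from the labels. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which left 13678 genes with 99.98% of the counts. Counts were scaled by TMM factors, and the 3 groups were fitted together with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Normalised counts (CPM) are counts relative to TMM-scaled library sizes, as given by the cpm function of edgeR; log2 CPM used a prior count of 2. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of a comparison. There were 31 lists: epithelial adhesion and keratin, intestinal stem cell, cancer stem cell and pluripotency, WNT target, NOTCH pathway, enterocyte, goblet and enteroendocrine, mesenchymal transition, YAP and TEAD target, G1/S, G2/M, cell cycle exit and quiescence, replication-dependent histone, ion channel, ion pump and ion transporter, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis, hypoxia, cholesterol synthesis, ribosomal protein, ER stress and amino acid response, heat shock, immediate early, NF-kB target and chemokine, interferon-stimulated, apoptosis regulator, drug efflux transporter and nuclear-retained long RNA genes, and markers of blood and immune cells and of fibroblasts and endothelial cells. "Adjusted over the list alone" means Benjamini-Hochberg over the tested members of one list.

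Genes were named by a rule. Per direction, it took the 8 genes with the largest log2 fold change among those passing, with a mean CPM of at least 1 and no overlap between the groups' libraries, leaving out pseudogenes and unnamed loci. Where none passed, it took the 3 genes per direction with the lowest p. It added up to 4 members with the lowest p, in the list's direction, from each list that passed camera, and a set of markers of stemness, epithelium, mesenchyme and proliferation. The mitochondrial share was compared by exact permutation tests over all 70 assignments of 4 and 4 libraries. The position of PT was computed per gene as the PT mean minus the F3 mean, divided by the F1 mean minus the F3 mean.

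The fit was tested on simulated counts drawn from the real means, library sizes and dispersions of the 13678 genes, with 200 genes changed and the epithelial list lowered in F1. It recovered 58.6% of the genes changed 2-fold and 98% of those changed 4-fold, with 10 false calls among 167. A simulated mixture with an F1 share of 0.6 in PT was recovered as 0.581, over genes that were both changed by design and called. The simulated libraries were independent, without trends over length, GC content or replicate number. The recovery thus does not show that the position of PT in the real data is an F1 share.

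Replicate numbers are shared by the groups, and the design text does not say that a number marks a culture. The correlations of same-numbered libraries' deviations from their group means were checked. For F3 and PT all 4 lay between 0.154 and 0.566, and these libraries were taken as paired from these data. The main values of this comparison still come from the fit without a block, and what the block changed is given after them. F1 was not taken as paired with F3 or PT, because of negative r for F1 and F3 replicate 1 (-0.17) and for F1 and PT replicate 3 (-0.10). These pairs hold F1 replicate 1, with a trend over transcript length, and PT replicate 3, with one over GC content. Their r thus does not show separate cultures. The other same-numbered libraries had r of 0.40 to 0.51 for F1 and F3 and 0.10 to 0.74 for F1 and PT, so shared cultures are not excluded.

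Alternatives tried were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, other filters on low counts, a fit to the 8 libraries compared, the replicate number as a block, an estimated correlation for lists, other scales for the position of PT, and leaving out each library in turn. Settings added after the data were seen left out F1 replicate 1 and PT replicate 3 together, and used offsets for transcript length and GC content (GENCODE transcripts, known for 13483 of the tested genes), with and without the block. Figures were drawn with matplotlib 3.10.9.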

Results

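RNA was sequenced from SW480, an established human colorectal cancer cell line, after sedimentation field-flow fractionation (SdFFF). In this method a liquid stream carries cells through a spinning channel, and the time at which a cell leaves depends on physical properties such as its size and density. The populations were collected at a field of 12 g (270 rpm) and a flow of 1.0 mL per min. Fraction F1 left the channel early, from 3 min 20 s to 4 min 30 s after injection. Fraction F3 left late, from 6 min 0 s to 7 min 50 s. PT, the total eluted population, spanned 3 min 20 s to 7 min 50 s, so its window holds those of both fractions. Each population had 4 replicate libraries, 12 in all, which the submitters describe as coming from independent cultures. The table held counts for 18856 genes, and each library summed to between 29030028 and 30453559 counts, so depth differed little between groups. Of these genes, 13678 had counts high enough to be tested.

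The series concerns stem-like states in a colorectal cancer line, and the comparison of F1 with F3 asks how cells that left the channel early and late differ in gene expression. KRT13, a keratin of stratified epithelia, was 5.54-fold lower in F1 (28.5 ± 12.6 CPM, SD, n = 4) than in F3 (158 ± 77.2 CPM, n = 4), a log2 fold change of -2.47 (SE 0.37). CDH1, which encodes the cell adhesion protein E-cadherin, was at 3.87 ± 1.68 CPM in F1 and 13.9 ± 2.55 CPM in F3, 3.57-fold lower in F1. SCNN1A, a subunit of the epithelial sodium channel, was at 19.7 ± 1.73 CPM in F1 and 56.9 ± 10.8 CPM in F3, with a log2 fold change of -1.53 (SE 0.16). HHIP, a membrane protein that binds Hedgehog ligands, went the other way, with 2.58 ± 0.537 CPM in F1 and 0.624 ± 0.322 CPM in F3 (log2 fold change 2.05, SE 0.37). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0207 for KRT13, 0.0432 for CDH1, 0.00171 for SCNN1A and 0.0379 for HHIP. On GRCh38.p14, KRT13 lies on chromosome 17 (41500981 to 41505612), CDH1 on chromosome 16 (68737292 to 68835537), SCNN1A on chromosome 12 (6346847 to 6377359) and HHIP on chromosome 4 (144646156 to 144745271).

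**Figure D1:**
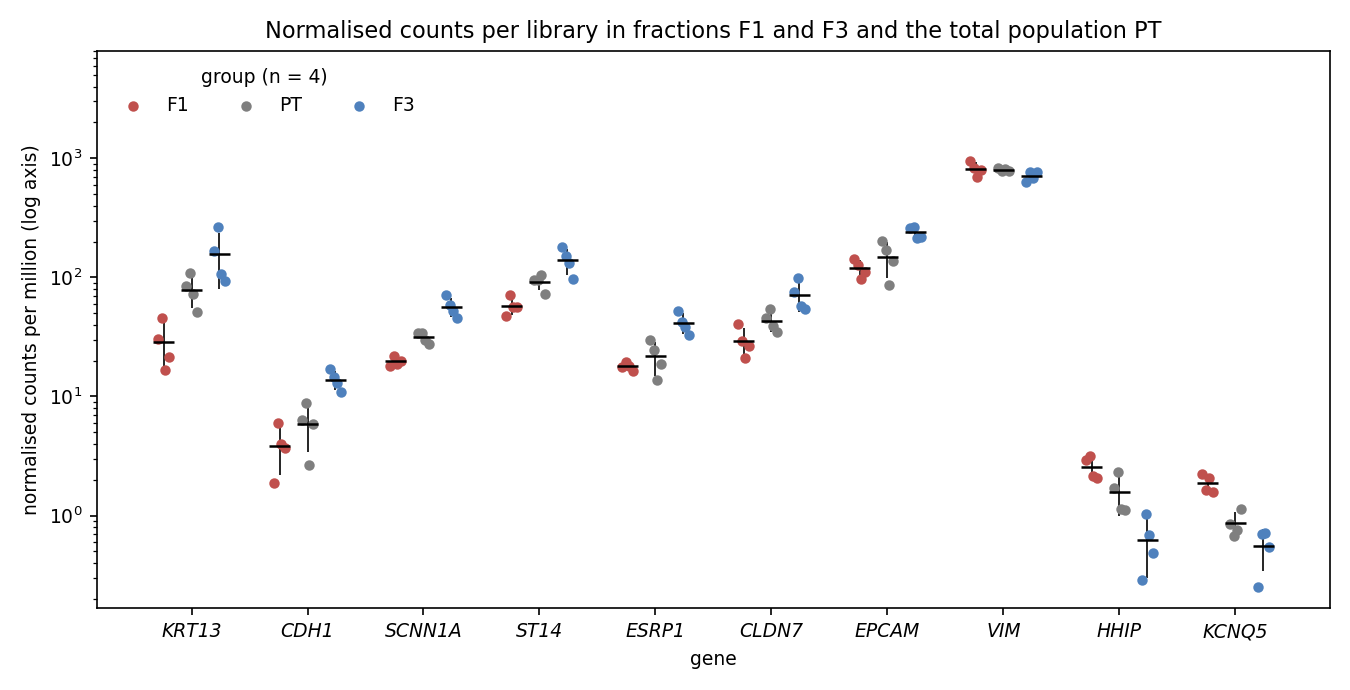
Normalised counts in CPM (log axis) of 10 genes in each library of F1, PT and F3 (points; bars give the mean, lines the SD, n = 4 per group). For KRT13, CDH1, SCNN1A, ST14, ESRP1, CLDN7 and EPCAM the F3 points lie above the F1 points; HHIP and KCNQ5 show the opposite order, and for VIM the groups overlap.

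In all, 51 genes differed between F1 and F3, of which 48 were lower in F1 and 3 were higher. In 47 of the 51 the difference was at least 2-fold, 44 of them lower in F1. Over all 13678 tested genes, the 4 F1 libraries lay on one side of the 4 F3 libraries for 729 (5.33%), where chance gives 2.86%; all 51 genes were among them. Besides KRT13 and CDH1, the genes with the largest decreases in F1 were SGPP2 (log2 fold change -2.26, SE 0.40), a sphingosine phosphate phosphatase, CAPN8 (-2.22, SE 0.38), a calpain protease, CADPS (-2.20, SE 0.43), which acts in vesicle exocytosis, SLC26A4 (-1.97, SE 0.32), the anion exchanger pendrin, and the adhesion molecule NCAM1 (-1.81, SE 0.28). ANXA8L1 was also lower (-2.30, SE 0.37), but 81.7% of the 50-base words of its transcript also occur in the transcripts of other genes, chiefly ANXA8, so its value is uncertain. Other genes lower in F1, by log2 fold changes of -1.04 to -1.75, included MAL2 (58.9 CPM in F3), LAMA3 (a laminin chain), CDH3 (P-cadherin), and SPINT1, which encodes an inhibitor of the protease matriptase. These 4 were chosen after their values were seen. The genes higher in F1 were HHIP, the potassium channel gene KCNQ5 (log2 fold change 1.76, SE 0.32, chromosome 6, 72622064 to 73198853) and the nuclear receptor gene NR5A2 (2.21, adjusted p = 0.0352 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). NR5A2 fell outside the rule for named genes because of its low mean level, 1.21 CPM in F1 and 0.259 CPM in F3, and was named after its value was seen. The count of 51 dropped to 1 without F1 replicate 3, 1 without F3 replicate 1 and 2 without F1 replicate 4. It was 16 without F3 replicate 2, 18 without F3 replicate 3 and 22 without F1 replicate 1. SCNN1A passed the edgeR test under all 8 omissions, and the potassium channel gene KCNS3 under 0 (lowest edgeR adjusted p 0.054). Each of the other called genes named from the rule passed under 1 to 5 of them. DESeq2 called 229 genes (53 higher and 176 lower in F1), which included all 51, and a fit to the 8 F1 and F3 libraries alone called 12, of which 9 were among the 51. With offsets for transcript length and GC content, added after the data were seen, edgeR called 181 genes (32 higher and 149 lower in F1), 49 of them among the 51. With the replicate number as a block, edgeR called 245 genes (94 higher and 151 lower in F1), which included all 51. The balance of higher and lower genes thus depended on the fit.

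Genes of epithelial adhesion and keratins were lower in F1 as a group. Of the 22 tested members of this list, 5 fell when adjusted over all genes (CDH1, CLDN7, ESRP1, ST14 and CDS1) and 12 fell when adjusted over the list alone. None rose, and 20 of the 22 had negative log2 fold changes, with a median of -0.53. CLDN7, a tight junction claudin, went from 71.5 ± 20.5 CPM in F3 to 29.4 ± 8.26 CPM in F1 (n = 4 each), and ST14, the matriptase gene, from 140 ± 34.8 to 57.8 ± 9.76 CPM. ESRP1, an epithelial regulator of splicing, was at 41.7 ± 8.30 CPM in F3 and 17.9 ± 1.37 CPM in F1. EPCAM, an epithelial surface protein, was at 239 ± 25.4 CPM in F3 and 120 ± 20.2 CPM in F1 and did not pass over all genes (edgeR adjusted p = 0.0813), although its libraries did not overlap. The list passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 2.35e-22) and with an estimated one (adjusted p = 0.00382 with an estimated correlation), the only list of 30 to pass both. It passed the preset test under each of the 8 omissions of one library, with medians of -0.60 to -0.48.

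None of the stem cell and mesenchymal markers passed over all genes in the fit without a replicate block. LGR5, a marker of intestinal stem cells, was near the floor of the assay, with 0.826 ± 0.604 CPM in F1 and 0.258 ± 0.161 CPM in F3 (n = 4), and its edgeR adjusted p was 0.534. ASCL2 was at 45.1 ± 21.7 CPM in F1 and 53.4 ± 13.5 CPM in F3, CD44 at 188 ± 56.2 and 148 ± 37.8 CPM, and SOX9 at 177 ± 51.4 and 210 ± 22.5 CPM. PROM1, ALDH1A1 and KRT20 had 42, 45 and 101 counts over the 12 libraries and were too low to test. The mesenchymal intermediate filament gene VIM was at 816 ± 110 CPM in F1 and 711 ± 68.5 CPM in F3. ZEB1, a repressor of CDH1, was at 14.8 ± 2.11 CPM in F1 and 9.74 ± 3.50 CPM in F3, a log2 fold change of 0.60 (SE 0.29). For ASCL2, CD44, SOX9, VIM, ZEB1, MYC, CDX2, CCND1, CDKN1A, MKI67 and BMI1 the edgeR adjusted p lay between 0.677 (ZEB1) and 0.933 (MYC). Taken by replicate number, LGR5 was at 0.58, 0.095, 1.21 and 1.42 CPM in F1 and 0.25, 0.034, 0.36 and 0.39 CPM in F3. LGR5, ZEB1 and VIM were thus higher in F1 for each number, while ASCL2, CD44, SOX9, BMI1 and MYC went both ways. A difference in these markers is not excluded. BMI1 shares its locus with a read-through gene, so its value is uncertain. Tested list members were 18 intestinal stem cell genes, 22 cancer stem cell and pluripotency markers and 21 mesenchymal transition genes. In the fit without a block, no member of these lists passed over all genes. Adjusted over the list alone, 1 cancer stem cell marker rose (LIN28A, log2 fold change 3.71, edgeR adjusted p = 0.153 over all genes) and 1 fell (EPCAM). With the replicate number as a block, LIN28A passed over all genes (log2 fold change 3.75, edgeR adjusted p = 0.00115). The camera adjusted p values of these lists were 0.961, 0.689 and 0.86.

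The lists of G2/M, G1/S and ER stress and amino acid response genes were lower in F1 by small amounts, without single genes passing and only with the preset correlation. Of 55 G2/M genes, 49 had negative log2 fold changes (median -0.24), among them TOP2A, the topoisomerase of dividing cells, at 333 ± 86.8 CPM in F1 and 519 ± 52.5 CPM in F3, and HJURP at 52.1 ± 7.34 and 66.7 ± 2.82 CPM. The list passed camera (Benjamini-Hochberg adjusted p = 3.46e-08), with adjusted p = 0.357 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. Of 43 G1/S genes, 34 were negative (median -0.09), such as RRM2 at 395 ± 53.5 CPM in F1 and 497 ± 31.4 CPM in F3. Their camera adjusted p was 0.0148, against adjusted p = 0.792 with an estimated correlation and 0.159 without F1 replicate 1, and the median was -0.18 without F1 replicate 2; 0 members passed over all genes or adjusted over the list alone. Of 25 genes of the ER stress and amino acid response, 19 were negative (median -0.08) and the camera adjusted p was 0.00174 (adjusted p = 0.357 with an estimated correlation). The median was -0.126 without F1 replicate 2, -0.172 without F1 replicate 4, -0.126 without F3 replicate 1, -0.127 without F3 replicate 2 and -0.125 without F3 replicate 3. Adjusted over the list alone, 3 of them fell, and 0 passed over all genes. The members with the lowest p make amino acids or regulate that response: ASNS, asparagine synthetase, at 116 ± 21.9 CPM in F1 and 195 ± 30.5 CPM in F3, PHGDH, an enzyme of serine synthesis, at 108 ± 14.5 and 178 ± 35.7 CPM, and TRIB3 at 52.2 ± 3.19 and 79.6 ± 14.4 CPM.

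Ion channel genes went both ways. Of 46 tested, KCNQ5 rose and SCNN1A and KCNS3 (log2 fold change -1.09, SE 0.21), a modulatory potassium channel subunit, fell. KCNS3 passed over all genes under 0 of the 8 omissions of 1 library. Adjusted over the list alone, 1 rose and 3 fell. The list had a median of -0.10 and passed camera as lower in F1 (Benjamini-Hochberg adjusted p = 0.0204), with adjusted p = 0.388 with an estimated correlation and 0.249 without F1 replicate 1. The median was -0.0459 without that library and -0.055 without F3 replicate 1. Among 30 genes of ion pumps and ion transporters, 0 passed over all genes or adjusted over the list alone, and the camera adjusted p was 0.839. Of 13 drug efflux transporter genes, ABCC3, a multidrug resistance protein, fell (13.6 CPM in F1 and 34.2 CPM in F3; log2 fold change -1.33), as the single member also when adjusted over the list alone; the list did not pass camera (adjusted p = 0.164).

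Among the lists higher in F1, for 2 of 3 the direction turned on a single library. All 77 tested genes of cytosolic ribosomal proteins had positive log2 fold changes (median 0.50; camera adjusted p = 3.46e-08), with adjusted p = 0.906 with an estimated correlation. RPL38 was at 606 ± 436 CPM in F1 and 346 ± 77.9 CPM in F3, and RPS20 at 1201 ± 1036 and 690 ± 127 CPM. Of 44 nuclear genes of oxidative phosphorylation, 40 were positive (median 0.38; camera adjusted p = 0.000528), with adjusted p = 0.906 with an estimated correlation; COX6C was at 161 ± 128 CPM in F1 and 93.6 ± 15 CPM in F3. In neither list did a member pass over all genes or adjusted over the list alone. F1 replicate 1 stood apart in these libraries, with a TMM factor of 0.813 and a first principal component score of -57.95. Without it the median of the ribosomal protein list was -0.08 (camera adjusted p = 0.037, lower in F1) and that of the oxidative phosphorylation list -0.04 (0.413). With offsets for transcript length and GC content, added after the data were seen, the medians were 0.17 for the ribosomal protein list (camera adjusted p = 0.00048) and 0.12 for the oxidative phosphorylation list, which no longer passed (0.0561). Of 25 cholesterol synthesis genes, 24 were positive (median 0.19; camera adjusted p = 0.0138, or adjusted p = 0.434 with an estimated correlation), such as TM7SF2 at 96.5 ± 38.4 CPM in F1 and 66.7 ± 7.56 CPM in F3. No member passed over all genes or adjusted over the list alone, and without F3 replicate 1 the median was 0.12 and the camera adjusted p 0.0771.

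The other lists did not pass camera between F1 and F3, and none of their members passed over all genes. The camera adjusted p was 0.306 for WNT target genes, 0.273 for NOTCH pathway genes, 0.412 for YAP and TEAD target genes, 0.164 for cell cycle exit and quiescence genes and 0.511 for replication-dependent histone genes. It was 0.86 for enterocyte genes, 0.473 for goblet and enteroendocrine genes, 0.689 for the 13 mitochondrially encoded mRNAs, 0.86 for glycolysis genes and 0.396 for hypoxia response genes. For heat shock, immediate early, NF-kB target and chemokine, interferon-stimulated and apoptosis regulator genes it was 0.961, 0.338, 0.961, 0.648 and 0.961. Markers of cell types foreign to this line were scarce: 5 of 17 blood and immune cell markers and 7 of 16 fibroblast and endothelial cell markers could be tested, each with a camera adjusted p of 0.164. Adjusted over the list alone, 1 YAP and TEAD target gene and 1 blood and immune cell marker rose, and 1 enterocyte gene, 2 goblet and enteroendocrine genes and 1 interferon-stimulated gene fell. Of the nuclear-retained long RNAs 1 could be tested, so the list was not. The camera direction was down while the median was positive for goblet and enteroendocrine, NF-kB target and chemokine, and ion pump and ion transporter genes, and down with a positive mean for intestinal stem cell, heat shock and apoptosis regulator genes.

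**Figure D2:**
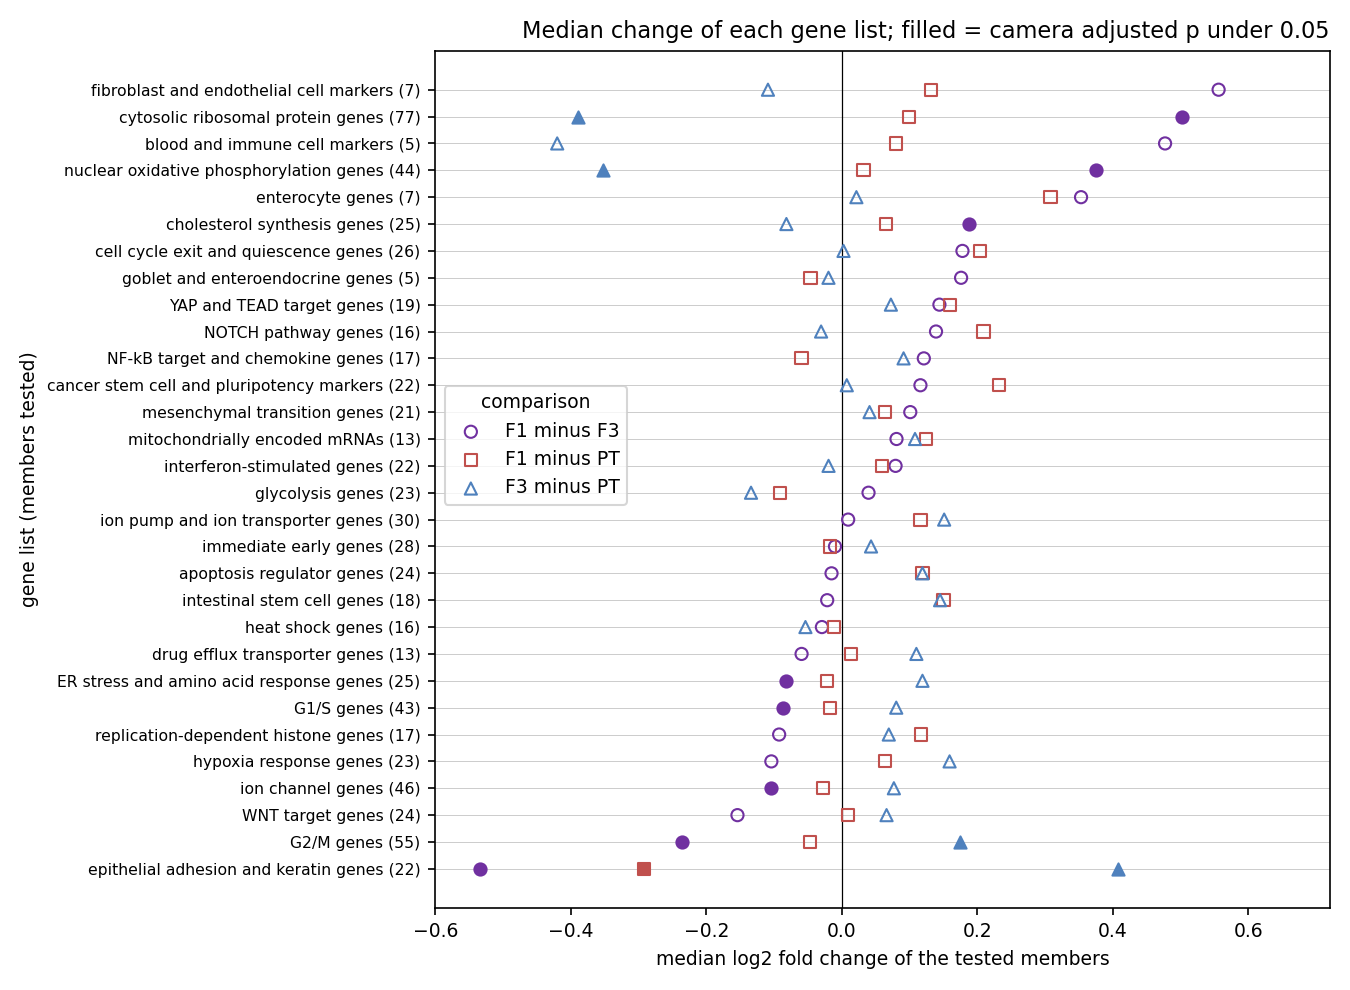
Median log2 fold change (horizontal axis) of the tested members of each gene list (rows; number tested in parentheses) for F1 minus F3 (circles), F1 minus PT (squares) and F3 minus PT (triangles); filled symbols passed camera with a preset correlation. Epithelial adhesion and keratin genes had medians of -0.53, -0.29 and 0.41.

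The comparison of F1 with PT asks how the early fraction differs from all eluted cells. Epithelial adhesion and keratin genes were lower in F1: 17 of 22 had negative log2 fold changes, with a median of -0.29. ST14 was at 57.8 ± 9.76 CPM in F1 and 91.9 ± 13.6 CPM in PT (n = 4 each), and KRT19, a keratin of simple epithelia, at 941 ± 117 and 1307 ± 231 CPM. The plakophilin gene PKP3 was at 60.5 ± 6.73 CPM in F1 and 87.1 ± 23.5 CPM in PT. The list passed camera (Benjamini-Hochberg adjusted p = 1.73e-06), the single list of 30 to do so, with adjusted p = 0.177 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. No gene passed the edgeR quasi-likelihood test (smallest Benjamini-Hochberg adjusted p 0.972), nor DESeq2 or limma-voom (0 genes each). In edgeR 378 had an unadjusted p under 0.05, where 683.9 would be reached by chance. That count was 185 without F1 replicate 3, 2003 without F1 replicate 1 and 757 with the replicate number as a block. It thus lay below or above the chance value depending on the setting. With the block edgeR called 1 gene, KRT13 (log2 fold change -1.53, adjusted p = 0.0323). The genes with the lowest p, which did not pass, were SCNN1A (19.7 ± 1.73 CPM in F1, 31.5 ± 3.41 CPM in PT), ADRA1B (2.00 ± 0.286 and 3.62 ± 0.228 CPM) and ANXA8L1 on the lower side, and KCNQ5 (1.89 ± 0.316 and 0.858 ± 0.203 CPM), ZNF708 and ASDURF on the higher side. The count of lists was 6 without F1 replicate 1, F1 replicate 2, PT replicate 3 or PT replicate 4. It was 5 without PT replicate 2 and 2 without F1 replicate 3 or F1 replicate 4. With the replicate number as a block it was 6. With offsets for transcript length and GC content, added after the data were seen, it was 7. The epithelial list was among them each time. Without F1 replicate 1 the ribosomal protein list, which did not pass with all libraries (median 0.0992, 64 of 77 positive, camera adjusted p = 0.307), was lower in F1 (median -0.455, 0 of 77 positive, camera adjusted p = 1.99e-37).

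The comparison of F3 with PT asks the same of the late fraction. Epithelial adhesion and keratin genes were higher in F3: 18 of 22 had positive log2 fold changes (median 0.41), and 6 rose when adjusted over the list alone, against 0 over all genes. CDH1 was at 13.9 ± 2.55 CPM in F3 and 5.92 ± 2.53 CPM in PT (n = 4 each), ESRP1 at 41.7 ± 8.30 and 21.8 ± 7.02 CPM, and CLDN7 at 71.5 ± 20.5 and 43.2 ± 8.55 CPM. The list passed camera (Benjamini-Hochberg adjusted p = 9.49e-09), with adjusted p = 0.101 with an estimated correlation. G2/M genes were higher in F3 (39 of 55 positive, median 0.18; camera adjusted p = 0.00132, or adjusted p = 0.714 with an estimated correlation), such as KIF20B, a mitotic kinesin, at 31.3 ± 4.37 CPM in F3 and 21.1 ± 7.23 CPM in PT. All 77 ribosomal protein genes were lower in F3 (median -0.39; camera adjusted p = 4.57e-13, or adjusted p = 0.717 with an estimated correlation), as were 42 of 44 nuclear oxidative phosphorylation genes (median -0.35; camera adjusted p = 4.64e-09, or adjusted p = 0.714 with an estimated correlation). RPL35 was at 797 ± 148 CPM in F3 and 1200 ± 301 CPM in PT, and ATP5MC1 at 73.1 ± 10.9 and 104 ± 23.4 CPM. In these 3 lists 0 members passed over all genes or adjusted over the list alone. PT replicate 3 stood apart from the other PT libraries with a first principal component score of -52.84 and a TMM factor of 0.917; without it 7 lists passed, and 7 also without F3 replicate 4, each time with the same 4 among them. Without PT replicate 3 the median of the G2/M list was 0.0905 and that of the oxidative phosphorylation list -0.23.

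No single gene passed the edgeR quasi-likelihood test between F3 and PT (smallest Benjamini-Hochberg adjusted p 0.736), nor limma-voom. In edgeR 480 had an unadjusted p under 0.05, where 683.9 would be reached by chance. With the replicate number as a block that count was 905. Leaving out 1 library gave 177 (F3 replicate 1) to 1009 (PT replicate 2). DESeq2 called 1 gene, SCNN1A (log2 fold change 0.85, DESeq2 adjusted p = 0.00236), at 56.9 ± 10.8 CPM in F3 and 31.5 ± 3.41 CPM in PT. The genes with the lowest p, which did not pass in edgeR, also included ESRP1 and LAMA3 (33.5 ± 4.55 CPM in F3, 17.3 ± 4.00 CPM in PT) on the higher side and SYDE1, MAGEH1 and HHIP (0.624 ± 0.322 and 1.58 ± 0.575 CPM) on the lower side. Same-numbered F3 and PT libraries deviated together, so this comparison was also fitted with the replicate number as a block, beside the main fit without it. The smallest edgeR adjusted p with the block was 0.305. The block left the count of genes at 0 and added the list of fibroblast and endothelial cell markers, lower in F3 (camera adjusted p = 0.0104 with the block, 0.184 without; adjusted p = 0.714 with an estimated correlation and no block). With both the block and offsets for transcript length and GC content, a setting added after the data were seen, edgeR called 56 genes (50 higher and 6 lower in F3) and camera 11 lists. In that fit the medians were -0.207 for ribosomal protein genes, -0.169 for oxidative phosphorylation genes, 0.0827 for G2/M genes and 0.405 for epithelial genes. Of the 56, 22 were among the 51 that differed between F1 and F3; MAL2 (log2 fold change 0.88, SE 0.08), SCNN1A (0.90, SE 0.08) and KRT13 (1.14, SE 0.12) led them, with edgeR Benjamini-Hochberg adjusted p of 0.00534, 0.00534 and 0.00722.

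PT lay between the fractions for every gene that differed between them. These genes were picked from the same data for a gap between F1 and F3. A PT mean between the 2 is thus likely by selection alone, and does not show that PT mixes the fractions. For the 51 genes, the position of the PT mean on the scale from F3 (0) to F1 (1) had a median of 0.617 (quartiles 0.533 and 0.685), and all 51 lay between 0 and 1. KRT13 was at 28.5, 79.1 and 158 CPM in F1, PT and F3, and HHIP at 2.58, 1.58 and 0.624 CPM. The 4 PT libraries taken singly gave 0.552, 0.49, 0.656 and 0.781 (SD 0.128), and on the log2 scale the median was 0.481.

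**Figure D3:**
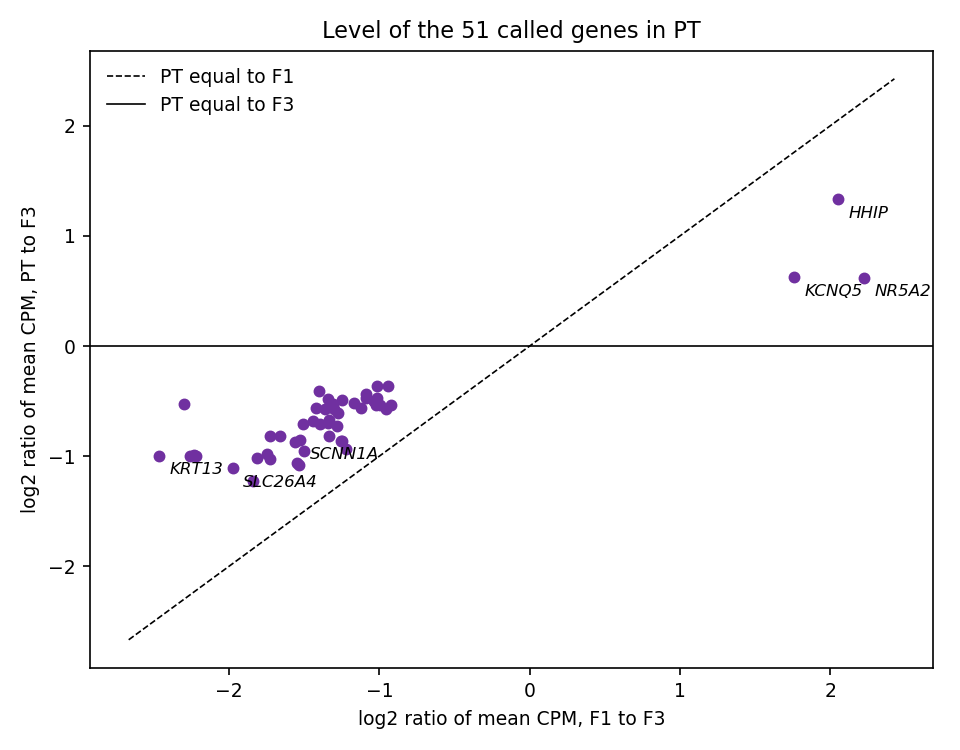
Log2 ratio of mean CPM in PT to F3 (vertical axis) against that in F1 to F3 (horizontal axis) for the 51 genes that differed between F1 and F3 (points). All lie between the lines for a PT level equal to F3 (solid) and equal to F1 (dashed).

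The directions of the fractions against PT were compared gene by gene. No gene passed the edgeR test against PT in either fraction (F1 378 and F3 480 genes at an unadjusted p under 0.05; DESeq2 0 and 1), so the overlap of calls was 0. At an unadjusted p under 0.05, 53 genes went in opposite directions and 10 in the same direction. Because both comparisons use the same PT libraries, unchanged simulated groups gave 0.8 and 145.4 genes, and independent lists of these sizes would share 6.46 and 6.81. The simulation drew every library independently, without the likeness of same-numbered libraries, so its values are not a like measure for the observed counts. The observed counts also ignore that likeness: with the replicate number as a block, 757 (F1) and 905 (F3) genes had an unadjusted p under 0.05 against PT. With the PT libraries split into pairs, 1 pair for each fraction, 20 to 160 genes went in opposite directions and 0 to 2 in the same direction.

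The share of counts from the 13 mitochondrially encoded mRNAs differed between the populations by no more than the spread between replicates. It was 6.07% ± 1.08 (SD, n = 4) in F1, 5.67% ± 1.3 in F3 and 5.15% ± 0.708 in PT. Exact two-sided permutation tests over all 70 assignments gave p = 0.657 for F1 against F3, 0.229 for F1 against PT and 0.543 for F3 against PT, with 0.657 as the Benjamini-Hochberg adjusted value of each of the 3; the smallest p this design allows is 0.0286. The difference between F1 and F3 was 0.392 percentage points, and -0.186 without F3 replicate 1.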

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

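Some tests were chosen only after the result was seen: that of shared sequence, when the called genes were known, that of ribosomal protein genes without F1 replicate 1, when high ribosomal counts in that library were known, and that of chromosome 13 copies; the omission of F1 replicate 1 with PT replicate 3 and the length and GC offsets were likewise added after the data were seen.

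In 171 groups of 4 libraries, 1 library lay far from the other 3 in 7 cases; chance gives about 1 in 20, or 8.55. NDUFB11 was at 603 CPM in F1 replicate 1 and at most 194 CPM in the other F1 libraries. MVK was at 38.7 CPM in F1 replicate 1, against 25.9 to 27.2 CPM. BMI1 was at 2.98 CPM in F1 replicate 1, against 20.3 to 29.2 CPM. CD44 was at 105 CPM in F1 replicate 2, against 200 to 224 CPM, and CCND1 at 1660 CPM in the same library, against 979 to 1070 CPM. RPS20 was at 878 CPM in F3 replicate 2, against 615 to 652 CPM, and CDKN1A at 121 CPM in PT replicate 1, against 151 to 156 CPM.

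The first pattern is the lower level of epithelial genes in F1 than in F3. The count of calls and the shared sequence below concern all called genes, of which 5 are on the epithelial list. The 51 genes called by edgeR were reached by 1 of the 35 splits of these 8 libraries, the real one. The highest of the others called 0. If the libraries are independent, that share is under 0.05, but it is the smallest that 35 splits allow, so chance is not excluded. If their numbers marked shared cultures, only 8 splits would be comparable, too few for a share under 0.05. Sequence shared with other genes covers at least 50% of 2 of the 48 genes lower in F1 (ANXA8L1 and BUB1B-PAK6), which argues against shared reads for the called genes. From the epithelial list, CDH1, CDS1, CLDN7, ESRP1 and ST14 shared 0% of their 50-base words. Without F1 replicate 1 and PT replicate 3 the epithelial list kept a median log2 fold change of -0.531, and without F1 replicate 1 alone of -0.529. With length and GC offsets the median was -0.518, against -0.534 in the main fit. These values argue against the quality of F1 replicate 1 and against sequence composition as the source. PT replicate 3 is in neither fraction, so its omission tests little here. What the difference reflects in the cells was not tested.

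The second pattern is the higher level of ribosomal protein genes in F1. Without F1 replicate 1 the median of the list was -0.075, and with length and GC offsets it was 0.173, against 0.502 with neither. With the offsets 72 of 77 genes stayed positive and the list still passed camera (adjusted p = 0.00048). The pattern may come from F1 replicate 1, from transcript length and GC content, or from both: that library's deviations over genes had r = -0.612 with log2 transcript length. No biological explanation was tested. The number of lists passing camera could be chance: 26 of the 35 splits of the F1 and F3 libraries gave as many as the real 8, and the highest of the others gave 17, in a split with F1 replicates 1, 2 and 3 and F3 replicate 1 on one side. Splits with more lists than the real one point to a structure of the libraries other than their groups. Taken list by list, 1 of 35 splits gave the epithelial list a camera p as small as the real one, 1 of 35 the G2/M list, and 34 of 35 the ribosomal protein list. For the other lists that passed, it was 4 for ER stress and amino acid response, 5 for G1/S, 6 for cholesterol synthesis, 6 for ion channel and 31 for oxidative phosphorylation genes. Chance is thus not excluded for these lists.

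Chance cannot be excluded for the number of lists against PT. For F1 against PT 35 of 35 splits gave at least the real 1 list (highest other 13), and for F3 against PT 33 of 35 gave at least the real 4 (highest other 14). No gene was called against PT in the real split (highest other 1 for F1 and 0 for F3), a count that all 35 splits reach whatever the data, so nothing follows from it about chance. No other split gave the epithelial list a camera p as small as the real one in either comparison (1 of 35 each). For F3 against PT, 2 of 35 splits, counting the real one, did so for the ribosomal protein list. It was 3 for the oxidative phosphorylation list and 6 for the G2/M list. Same-numbered F3 and PT libraries deviate together, so the real split is best compared with the 7 others that also part all 4 pairs: these gave 0 genes each and 1 to 6 lists, 5 of the 7 with at least the real 4. The remaining splits keep at least 1 pair together.

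The third pattern lies on chromosome 13. The 186 expressed genes of that chromosome had a median log2 fold change of -0.20 between F1 and F3, against 0.01 for the other autosomes, and 157 of them were lower in F1. Of 10000 draws of genes from other autosomes with like transcript length, GC content and expression, 0 had a median as low, and leaving out any 1 library left the difference from other genes at -0.184 or lower, which argues against sequence composition and a single library. Along the chromosome the differences from other genes in 4 consecutive windows were -0.35, -0.23, -0.23 and -0.0937; of 250 windows on other autosomes 0 were as low as the first. Fewer copies of the chromosome in F1 cells remain possible; the last window, 66 genes from 72782133 to 114327322, came short of the uniform shift of 0.1 that was asked for, which keeps this open. Camera over 22 autosomes gave chromosome 13 an adjusted p of 2.91e-08 by Benjamini-Hochberg and chromosome 15 (median -0.06) one of 0.0106, and both 0.985 with an estimated correlation.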

How the results depend on the processing

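The main tests, the gene lists and the alternatives other than the combined omission of F1 replicate 1 and PT replicate 3 and the length and GC offsets were chosen before the data were examined; those were added after. Under the alternatives chosen beforehand that leave out no replicate, 100 of 112 values of called named genes kept their call and 12 lost it, and 479 of 489 values of other named genes stayed without one and 10 gained it. With 1 library left out, 85 of 128 values of called genes lost their call. For genes between F1 and F3, DESeq2 called 229 and a fit to these 8 libraries alone 12; leaving out 1 library gave 1 to 59, and the cause was not tested. Size factors, limma-voom and other filters gave 50 to 61 genes. Offsets for length and GC content raised the count to 181, 49 of them shared with the 51. The combined omission gave 72 genes, 34 of them shared. Against PT the counts stayed at 0 with RLE size factors, limma-voom, other filters and each omission, and DESeq2 called 1 between F3 and PT (SCNN1A). With the replicate block, edgeR called 245 genes between F1 and F3 (94 higher and 151 lower in F1), including all 51, and 1 between F1 and PT (KRT13). With block and offsets it called 967 genes between F1 and F3 (436 higher and 531 lower in F1), 6 between F1 and PT and 56 between F3 and PT. With the block LIN28A was also called between F1 and F3 (log2 fold change 3.75, adjusted p = 0.00115). These numbers pair F1 with F3 or PT only as a hint from the data: the deviations of same-numbered libraries had r of -0.17 to 0.511 for F1 and F3 and -0.10 to 0.735 for F1 and PT, and 6 of 8 F1 and F3 libraries, 5 of 8 F1 and PT libraries and 7 of 8 F3 and PT libraries correlated best with their own number. The negative r values came from pairs that hold F1 replicate 1 or PT replicate 3, which stood apart from the other libraries. They thus do not show separate cultures. For F3 against PT the block changed no call but that of 1 list. The number of lists passing camera fell with an estimated correlation to 1 for F1 against F3, 0 for F1 against PT and 0 for F3 against PT. With 1 library left out it was 6 to 11, 1 to 6 and 4 to 7 in these comparisons. For F1 against PT it was 6 with the block, and 7 with the combined omission, with offsets, and with block and offsets; for F3 against PT it was 7, 8 and 11 in these last 3. Without F1 replicate 1, 2 lists reversed between F1 and F3: ribosomal protein genes (-0.075; range over omissions -0.075 to 0.669) and nuclear oxidative phosphorylation genes (-0.04; -0.04 to 0.531), and with the combined omission they were at -0.079 and -0.0424. Among single genes that did not pass, RPS20 (-0.0181; range -0.0181 to 1.01) and NDUFB11 (-0.0474; -0.0474 to 0.865) reversed without F1 replicate 1 and with the combined omission (-0.0218 and -0.0507), and MYC without F1 replicate 4 (-0.0745; -0.0745 to 0.334). The difference in mitochondrial share between F1 and F3 was -0.186 to 0.866 percentage points over omissions, the lowest without F3 replicate 1, with p of 0.343 to 0.971. The position of PT was 0.612 over genes with at least 2-fold differences and 0.481 on the log2 scale. The mitochondrial share without its ribosomal RNAs could not be run, because the table holds only the 13 mitochondrial mRNAs. At this depth PROM1, ALDH1A1 and KRT20 were too low to test, and LGR5 had 159 counts over the 12 libraries.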

Other observations

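The values for LIN28A and for the replicate numbers were chosen after the data were seen. LIN28A, an RNA-binding protein of embryonic and stem-like cells, had 106, 6, 154 and 123 counts in F1 replicates 1 to 4, 6, 1, 11 and 13 counts in F3, and 33, 0, 38 and 51 counts in PT. Its log2 fold change between F1 and F3 was 3.71 with edgeR adjusted p = 0.153 by Benjamini-Hochberg. With the block and the offsets for length and GC content it was also lower in F3 than in PT (log2 fold change -2.13, adjusted p = 0.0487). The genes that the same fit called higher in F3 than in PT included the lipocalin gene LCN2 (0.69, SE 0.08), the kallikrein protease genes KLK6 (0.56, SE 0.08) and KLK7 (1.13, SE 0.16), the integrin gene ITGB4 (0.46, SE 0.08) and the transcription factor gene OVOL2 (0.64, SE 0.11).

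Libraries numbered 2 stood apart in all 3 populations. For 1405 of 13678 genes the 3 libraries numbered 2 lay together above or below the other 9, where a random order gives 124; for the numbers 1, 3 and 4 there were 206, 183 and 215 such genes. ALPL, an alkaline phosphatase, had 63, 46 and 55 counts in the F1, F3 and PT libraries numbered 2 and 235 to 1247 counts in the other 9. MYBPH had 34, 17 and 24 counts there and 147 to 451 in the others, and ARSL had 16, 1 and 4 there and 89 to 309 in the others.

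PT replicate 3 had a trend with base composition: over expressed genes, its deviations from the mean of all libraries had r = 0.767 with the GC content of the transcript, against -0.486 to 0.375 in the other 11 libraries. Genes are not independent replicates. The chromosome 13 genes of that library lay 0.619 below the other genes on the log2 scale, and 0.137 below after length and GC trends were removed. After that removal the chromosome 13 difference from other genes was -0.08 ± 0.06 in F1 (SD, n = 4), 0.12 ± 0.05 in F3 and -0.02 ± 0.09 in PT. An exact two-sided permutation test gave p = 0.0286 for F1 against F3, the smallest this design allows, 0.286 for F1 against PT and 0.0571 for F3 against PT. As measured, the difference was -0.0413 ± 0.0808 in F1, 0.155 ± 0.0313 in F3 and -0.136 ± 0.336 in PT, with exact permutation p = 0.0286 for F1 against F3, 0.714 for F1 against PT, where F1 was the higher, and 0.0286 for F3 against PT. By same-numbered pairs F3 lay above PT in all 4, both as measured (0.0787 to 0.727) and with the trends removed (0.0716 to 0.238), and an exact sign-change test gave p = 0.125 for each, the smallest that 4 pairs allow. These p values are not adjusted, and the chromosome was picked after the data were seen.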
